A study of Rattus norvegicus with 6 samples.

How the data were processed

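RNA from the renal cortex of 6 male Sprague-Dawley rats was measured on 1-colour Agilent rat gene expression arrays, 1 array per animal. Per the labels' protocols, 3 rats received corn oil, the vehicle, and 3 received p-nitroanisole at 500 mg/kg per day, both for 4 weeks, and the rats were bought at 5 weeks of age. The labels call the samples of each group biological replicates from separate animals. The route of dosing and the time of necropsy are not given in the sources used here. Total RNA was converted to Cy3-labelled cRNA, per the labels' protocols.

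The deposited scanner files hold spot intensities from Agilent Feature Extraction 10.7.1.1, per the file headers (version 10.7 in the submitters' processing notes). The processed intensity of each spot had its background subtracted by the scanner software with spatial detrending, per the file headers, and was not scaled between arrays. The authors' deposited series matrix holds linear values that equal these processed intensities divided by 1 constant per array, which lay within 0.0241% of the array's 75th percentile over the mean of every probe, control probes included, with no centring per gene. The medians of its columns were 0.105, 0.105 and 0.105 for the vehicle arrays and 0.109, 0.108 and 0.111 for the treated arrays. Its scale and centring were thus found from the scanner values, and a 1-colour table has no ratio direction.

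Each array had 62976 spots, of which 1439 were control spots, leaving 61537 probes. Between 66.4% and 69.2% of the probes of an array were well above background, and their 75th percentile of the processed intensity, without control spots, lay between 877 and 1022. No spot was saturated. The number of arrays, 3 per group, limits the precision of every comparison. The files give an accession for each probe and no gene symbol. Symbols were taken by accession from a RefSeq gene table of the assembly GRCr8, which is not the build of the array design, so no coordinates are given. This named 28206 probes (45.84%), covering 15645 genes, and left 33331 probes unnamed here.

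The log2 processed intensity, floored at 1, minus each array's 75th percentile over non-control probes was used throughout. Control spots and spots with outlier flags (0 to 4 per array) were left out. A probe was tested if it was well above background on all 3 arrays of at least 1 group, which 41219 probes were. The tested probe with the highest mean level stood for each named gene, and unnamed probes stayed as rows of their own. This gave 32197 rows, 12207 of them named genes and 19990 unnamed probes. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust options, two-sided), with Benjamini-Hochberg adjustment over all rows and a threshold of 0.05.

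A total of 43 gene lists were fixed before the data were examined, with 878 of their 932 entries found on the array. The 42 lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation, and fry, which tests whether a list's genes move on balance in 1 direction, were run beside it. The members of each list were also adjusted over the list alone. The genes named in the text are the called genes with an official symbol whose groups do not overlap (up to 12 of the largest rises and falls), and for each list up to 4 called members or, with none called, the 2 tested members with the largest differences. For the called lists the 4 members with the largest differences were added by a rule set after the values were seen, and any other gene named was chosen after its values were seen. Some genes that these rules select are not reported here.

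The procedure was tested on simulated data of the same shape for p-nitroanisole against vehicle over 32194 genes. It recovered 2 of 67 genes changed by 0.5 on the log2 scale, 31 of 67 changed by 1 and 58 of 66 changed by 2, with 8 unchanged genes among the 99 called. The variances of the simulated genes were drawn from the distribution that limma fitted, with normal noise. These rates therefore hold under limma's own model and may differ on the real arrays. A list shifted by 0.5 was recovered and 0 lists that share no gene with it were called. The simulated genes varied independently of each other, while the correlation estimated in the real lists had a median of 0.0988. The simulation therefore cannot show how often camera calls a list of correlated genes by mistake. The alternatives, fixed before the data were examined, were quantile and median scaling, the series matrix values, other filters on dim probes, every probe as its own row, a trended robust variance, the slide or the replicate number as a block, a threshold of 0.01 and leaving out each array in turn. One further background correction was added after the files were seen. The file headers place the 3 vehicle arrays and treated replicates 1 and 2 on slide 1, and treated replicate 3 alone on slide 2, so a fit with slide as a block equals the comparison within slide 1.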

Results

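Transcript levels in the renal cortex were compared between 3 rats given p-nitroanisole, a methoxy-substituted nitrobenzene, at 500 mg/kg per day for 4 weeks and 3 rats given corn oil. Each animal had 1 array, with 40877 to 42601 of 61537 probes well above background. Arrays correlated across tested rows at r = 0.993 to 0.994 within the vehicle group. Treated replicates 1 and 2 correlated at 0.994, and treated replicate 3 with the other 5 arrays at 0.989 to 0.991. Genes are not independent replicates, so these values describe the arrays only. The first principal component (32.2% of the variance) placed all 3 treated arrays apart from the vehicle arrays. Treated replicate 3, which was on the second slide, lay at 47.4 on it, against 14.6 and 9.99 for treated replicates 1 and 2. On the second component (23.7%) treated replicates 1 and 2 lay at -28.83 and -32.98. The vehicle arrays lay at 8.68 to 12.4 and treated replicate 3 at 31.1. This split follows the row of the slide, 2 for treated replicates 1 and 2 and 1 for the other arrays.

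The comparison of the groups asks which transcripts differ in the cortex after 4 weeks of p-nitroanisole. The largest rise among named genes was that of Hmox1, the inducible heme oxygenase, which was 11.4-fold higher with treatment (log2 difference 3.51, SE 0.16, n = 3 per group, limma adjusted p = 0.0199). Alox15, a lipoxygenase of arachidonic and linoleic acid, rose 6.56-fold, and Ugt2b37, a glucuronosyltransferase, rose 4.36-fold. Alas2, the heme synthesis enzyme of red cell precursors, rose 3.75-fold, S100a8, a calcium-binding protein abundant in neutrophils, 3.44-fold, and the globins Hba-a3 and Hbb-b1 2.53-fold and 2.21-fold. The mitotic genes Kif2c, Cdc25b and Prc1 rose 2.45-fold, 2.28-fold and 2.25-fold, and the aldehyde dehydrogenase Aldh3b1 rose 1.83-fold. Matn1, a cartilage matrix protein, was 10.9-fold lower with treatment (log2 difference -3.45, SE 0.29) and Cyp2e1, a cytochrome P450 that oxidises small solvents, was 2.04-fold lower (log2 difference -1.03, SE 0.06). With the normexp background correction the log2 differences of Alox15, Kif2c and Matn1 were smaller, 2.10 against 2.71, 0.52 against 1.29 and -2.68 against -3.45. Of 16 alternatives, each of the 13 named genes lost its call in at least 4 (Hmox1) and at most 12 (Hbb-b1).

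**Figure D1:**
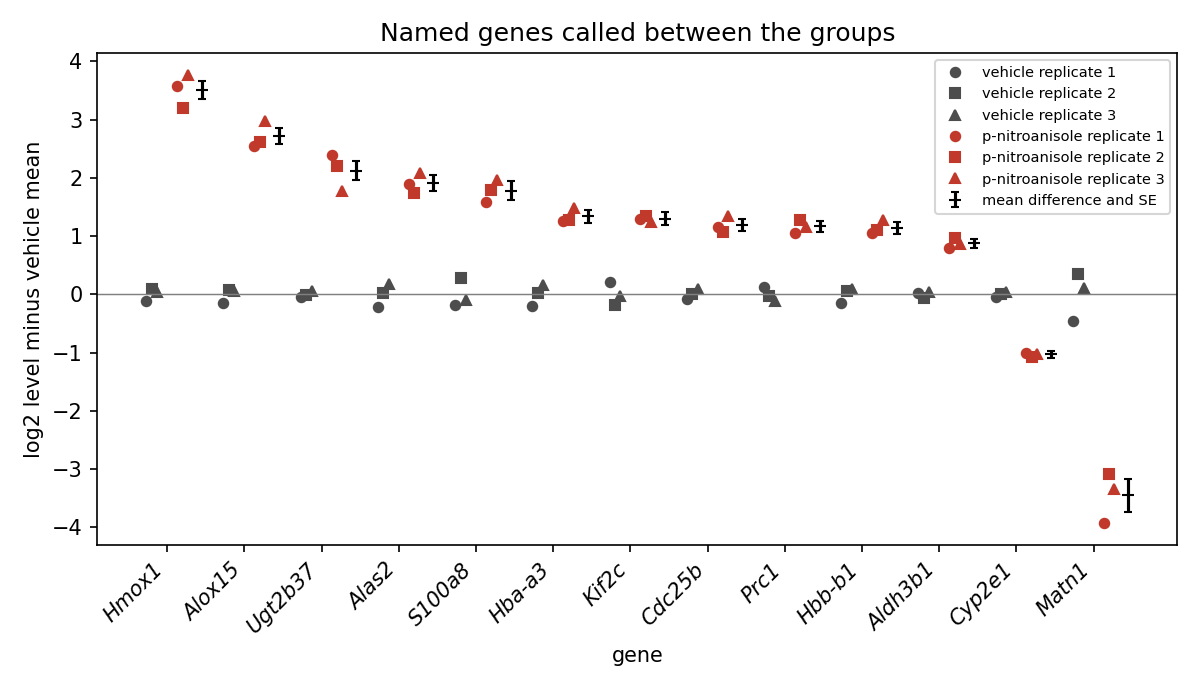
Log2 level of each called named gene on each array minus the mean of the 3 vehicle arrays (gray, vehicle; red, p-nitroanisole; 1 symbol per replicate number), with the mean difference and its SE from the limma fit in black. In all 13 genes the 3 treated arrays lie on 1 side of the 3 vehicle arrays, from 3.51 for Hmox1 to -3.45 for Matn1.

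These 13 named genes were among 24 rows called of 32197, 16 higher and 8 lower with treatment, with adjusted p between 0.0199 and 0.0491. Of the 24, 16 had a log2 difference of at least 1. The other 11 were unnamed probes, 5 higher and 6 lower, the largest rise being that of A_43_P19494 (4.02-fold) and the largest fall that of A_44_P557826 (2.66-fold lower). At an unadjusted p under 0.05 there were 4327 rows, 2474 higher and 1853 lower, and in 7143 rows (22.2%, against 10% by chance) the groups did not overlap. The other probes of the called named genes differed in the same direction, although the second Ugt2b37 probe gave a log2 difference of 0.40 (SE 0.22), that of Prc1 0.77 (SE 0.20), that of Matn1 -2.78 (SE 0.30) and that of Hba-a3 4.46 with a wide error (SE 2.27). Probes of related globin genes can share sequence, so neither globin is told apart from its related globin genes with certainty.

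Single-gene calls depended on the set of arrays. Without vehicle replicate 1, 2 or 3 limma called 1, 0 and 7 rows (3402, 3261 and 3336 at an unadjusted p under 0.05). Without treated replicate 1, 2 or 3 limma called 0, 5 and 9 (3720, 4239 and 4362). The direction of the 24 rows could not change in these fits, because their groups did not overlap. Within slide 1 (3 vehicle and 2 treated arrays) 9 rows were called, 3 of them among the 24, including Hmox1 (adjusted p = 0.0189) and Alox15 (adjusted p = 0.0181).

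Of the 42 gene lists tested, camera called 18, 11 higher and 7 lower with treatment. With an estimated correlation 0 of the 18 were called (8 of the 42 lists at an unadjusted p under 0.05), the smallest adjusted p being 0.238, while fry called 14 lists, 13 of them among the 18. Within slide 1, camera kept 14 of the 18 calls.

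Red cell genes as a list rose, with all 9 tested members higher and a median log2 difference of 1.39 (camera adjusted p = 5.3e-12; adjusted p = 0.238 with an estimated correlation). Alas2 and Hbb-b1 were called over all genes, and 8 members were higher when adjusted over the list alone. Rhd, a blood group antigen of red cells, had a log2 difference of 2.09 (SE 0.31, adjusted p = 0.113), Ahsp, the chaperone of alpha globin, 2.01 (SE 0.41, adjusted p = 0.165) and Hemgn, a nuclear protein of blood precursors, 1.98 (SE 0.48, adjusted p = 0.202; 1.06 with normexp). The median difference of its genes within slide 1 was 1.29. The neutrophil list also rose (7 tested, 6 higher, camera adjusted p = 0.00559; adjusted p = 0.254 with an estimated correlation). S100a8 was called, and 3 members were higher when adjusted over the list alone. S100a9, the partner of S100a8, differed by 1.54 (SE 0.17, adjusted p = 0.0662) and the antimicrobial peptide gene Camp by 0.47 (SE 0.13), against a list median of 0.12 (0.08 within slide 1, 0.22 and 0.30 without vehicle replicates 1 and 2, 0.06 with median scaling, 0.47 with no filter), and the call was lost without vehicle replicate 3 (adjusted p = 0.0585).

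Cell cycle genes rose as a list, 30 of 33 tested members being higher, with a median log2 difference of 0.60 (camera adjusted p = 4.06e-19; adjusted p = 0.238 with an estimated correlation). Prc1, which bundles microtubules in cell division, was the 1 member called over all genes, while 24 members were higher and 1 lower when adjusted over the list alone. The kinetochore gene Cenpf differed by 1.37 (SE 0.13, adjusted p = 0.0515; 0.70 with normexp, adjusted p = 0.0254), Ube2c, a ubiquitin-conjugating enzyme of mitosis, by 1.24 (SE 0.12, adjusted p = 0.0515), Rrm2, a subunit of ribonucleotide reductase, by 1.23 (SE 0.21) and the mitotic kinase Cdk1 by 1.22 (SE 0.16, adjusted p = 0.0902). The replication licensing gene Cdc6 was the lower member at -0.61 (SE 0.22). The median of the list was also 0.60 within slide 1.

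NRF2 targets, genes of the antioxidant response, rose as a list with 23 of 23 tested members higher and a median log2 difference of 0.49 (camera adjusted p = 1.42e-10; adjusted p = 0.238 with an estimated correlation). Hmox1 was called, and 12 members were higher when adjusted over the list alone. Gstp1, a glutathione transferase, differed by 1.45 (SE 0.26, adjusted p = 0.139), Gclm, a subunit of the rate-limiting enzyme of glutathione synthesis, by 1.17 (SE 0.49, adjusted p = 0.380; 0.40 with normexp and 0.65 within slide 1) and Akr1b8 by 1.51 with a wide error (SE 1.05), from 0.75 without vehicle replicate 1 to 2.52 within slide 1. Genes of glutathione and glucuronide conjugation rose too (32 tested, 23 higher, median 0.19, camera adjusted p = 0.00582; adjusted p = 0.238 with an estimated correlation), with 0 members called over all genes and 8 higher and 1 lower when adjusted over the list alone. Ugt2b15 differed by 2.07 (SE 0.25, adjusted p = 0.0805; 1.28 on its second probe), Ugt2b35 by 1.98 (SE 0.24, adjusted p = 0.0805) and Gstm1 by 1.81 (SE 0.42, adjusted p = 0.195), and the lower member was the sulfotransferase Sult1b1 at -0.81 (SE 0.19). The NRF2 median varied with the arrays used, from 0.33 without treated replicate 2 and 0.36 without vehicle replicate 1 or 2 to 0.75 without vehicle replicate 3. The conjugation median was 0.12 without vehicle replicate 2, with 17 of 32 members higher, 0.12 without treated replicate 2, with 20 higher, and 0.31 with no filter. The slide 1 medians of the NRF2 and conjugation lists were 0.61 and 0.19. With quantile scaling 22 of 23 NRF2 targets and 19 of 32 conjugation genes were higher. With median scaling 21 of 23 and 20 of 32 were higher. The conjugation call was lost with no filter on dim probes (adjusted p = 0.0508).

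**Figure D2:**
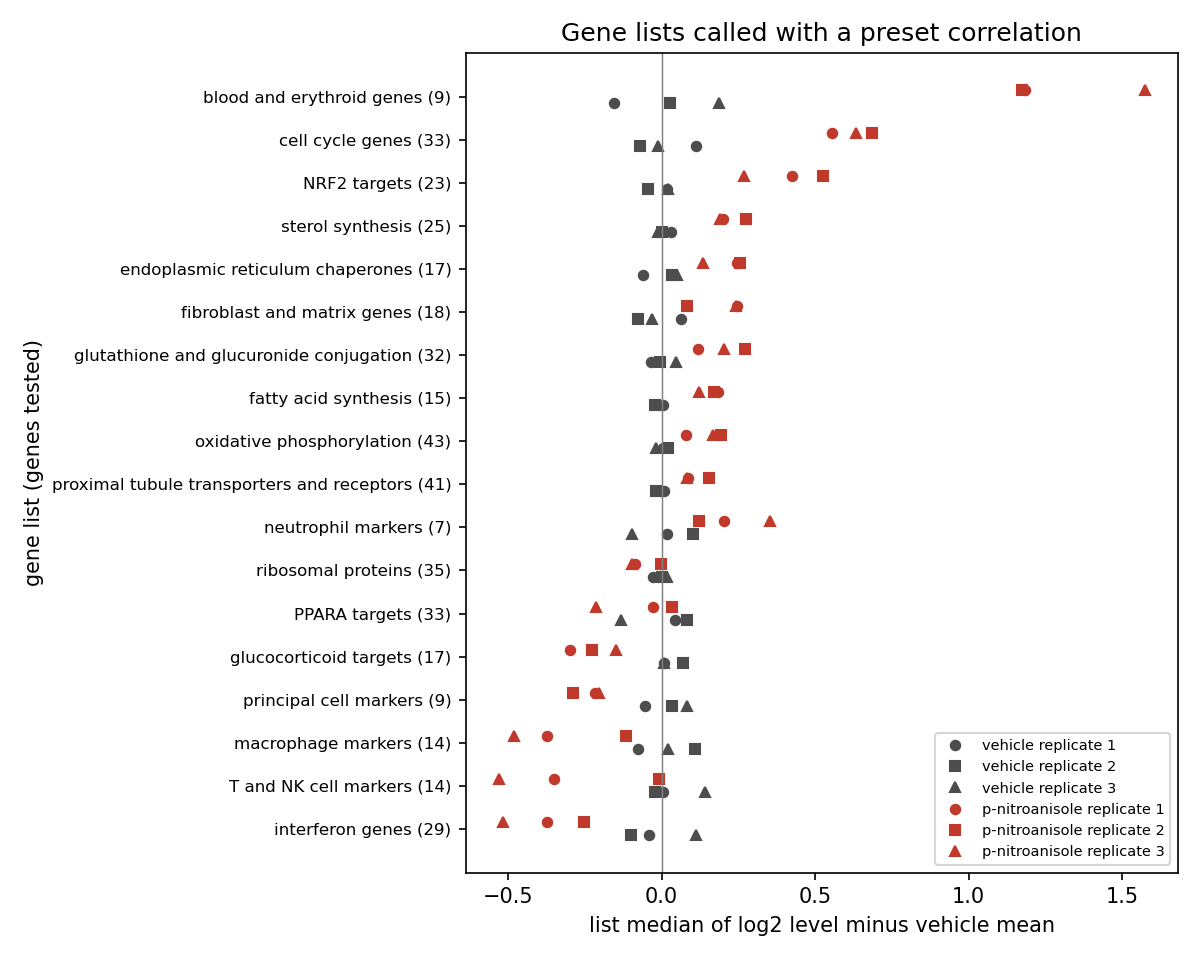
Median over the tested genes of each called list of the log2 level minus the vehicle mean, per array (gray, vehicle; red, p-nitroanisole; 1 symbol per replicate number), with the number of genes tested in parentheses. The treated arrays lie at 1.17 to 1.58 for red cell genes and at -0.25 to -0.52 for interferon genes.

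Sterol synthesis genes rose as a list, 24 of 25 being higher, with a median of 0.20 (camera adjusted p = 4.61e-10; adjusted p = 0.238 with an estimated correlation). No member was called over all genes and 12 were higher when adjusted over the list alone. Dhcr7, which catalyses the last step of cholesterol synthesis, differed by 0.88 (SE 0.11, adjusted p = 0.0813) and the isomerase gene Idi1 by 0.62 (SE 0.07, adjusted p = 0.0662). Fatty acid synthesis genes (15 tested, 13 higher, 2 when adjusted over the list alone, median 0.18, camera adjusted p = 0.00331; adjusted p = 0.238 with an estimated correlation) and endoplasmic reticulum chaperones (17 tested, 16 higher, 7 when adjusted over the list alone, median 0.20, camera adjusted p = 5.73e-06; adjusted p = 0.290 with an estimated correlation) rose as well. In the former Me1 differed by 0.73 (SE 0.14) and Fads2 by 0.42 (SE 0.09), in the latter Sdf2l1 by 0.73 (SE 0.14) and Hyou1 by 0.42 (SE 0.07). The sterol, fatty acid and chaperone lists had slide 1 medians of 0.22, 0.15 and 0.27.

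Small rises covered 3 further lists. All 43 tested oxidative phosphorylation genes were higher, with a median of 0.14, and 0 passed either over all genes or adjusted over the list alone (camera adjusted p = 1.4e-08; adjusted p = 0.343 with an estimated correlation), Ndufb8 at 0.31 (SE 0.09; 0.19 with quantile scaling) and Cycs at 0.28 (SE 0.08) among them. With quantile scaling 34 of the 43 were higher, with a median of 0.09, and with median scaling 37, with a median of 0.08. Proximal tubule transporters and receptors (41 tested, 31 higher, 2 when adjusted over the list alone, median 0.12) were called at camera adjusted p = 0.00379 (adjusted p = 0.238 with an estimated correlation), with the urate transporter gene Slc22a12 at 0.80 (SE 0.22) and Slc17a3 at 0.71 (SE 0.14). Their median was 0.03 with quantile scaling (27 of 41 higher), 0.07 with median scaling (26 higher) and 0.08 without vehicle replicate 1 (29 higher). Fibroblast and matrix genes (18 tested, 15 higher, 0 when adjusted over the list alone, median 0.19) were called at camera adjusted p = 0.00445 (adjusted p = 0.336 with an estimated correlation), although the member with the largest difference, Ccn2, was lower at -0.72 (SE 0.29; -0.41 without vehicle replicate 2). The last 2 calls were lost with no filter on dim probes (adjusted p = 0.0773 and 0.102). Within slide 1 the medians of the 3 lists were 0.12, 0.11 and 0.18.

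Interferon genes fell as a list, 27 of 29 tested members being lower, with a median log2 difference of -0.46 (camera adjusted p = 4.61e-10; adjusted p = 0.238 with an estimated correlation). Over all genes 0 members were called, and 11 were lower when adjusted over the list alone. Among these, Usp18, which removes the ubiquitin-like protein ISG15, differed by -0.97 (SE 0.17, adjusted p = 0.139; -0.61 and -0.98 on its other probes) and Oas1a, an RNA sensor, by -0.90 (SE 0.19, adjusted p = 0.165). Cxcl9, a chemokine of T cells, differed by -1.29 (SE 0.43, adjusted p = 0.303; -0.58 with normexp), while the antiviral gene Rsad2 ran the other way at 0.88 (SE 0.31, adjusted p = 0.321; 0.58 without vehicle replicate 2). Within slide 1 the list median was -0.35.

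T and NK cell markers fell, all 14 tested being lower, with a median of -0.35 (camera adjusted p = 0.00186; adjusted p = 0.329 with an estimated correlation), and so did macrophage markers, 12 of 14 being lower, with a median of -0.32 (camera adjusted p = 0.00167; adjusted p = 0.329 with an estimated correlation). In both lists 0 members passed over all genes or adjusted over the list alone. The granzyme gene Gzmb differed by -1.00 (SE 0.22; -0.47 with normexp) and the Fc receptor gene Fcgr3a by -1.00 (SE 0.42), while the mannose receptor gene Mrc1 was higher at 0.52 (SE 0.18). Within slide 1 the medians were -0.20 for T and NK cells and -0.23 for macrophages, and the T and NK call was lost there, without treated replicate 3 (adjusted p = 0.0990). The T and NK median of treated replicate 2, -0.01, lay within the range of the vehicle arrays (-0.02 to 0.14), against -0.35 and -0.53 on treated replicates 1 and 3. With the normexp background correction the T and NK list was still called lower (adjusted p = 0.00727) but its median was -0.09.

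Principal cell markers of the collecting duct fell (9 tested, 8 lower, median -0.26, camera adjusted p = 0.00151; adjusted p = 0.238 with an estimated correlation). The vasopressin receptor gene Avpr2 at -0.41 (SE 0.06) was the 1 member lower when adjusted over the list alone, and 0 were called over all genes. Its slide 1 median was -0.26. Glucocorticoid targets (17 tested, 13 lower, median -0.19, camera adjusted p = 0.0272; adjusted p = 0.238 with an estimated correlation), ribosomal proteins (35 tested, 28 lower, median -0.07, camera adjusted p = 0.00582; adjusted p = 0.550 with an estimated correlation) and PPARA targets (33 tested, 22 lower, median -0.09, camera adjusted p = 0.0481; adjusted p = 0.705 with an estimated correlation) were called lower, with 0 members past the threshold over all genes or adjusted over the list alone. The kinase gene Sgk1 differed by -1.21 (SE 0.35) and Fabp1 by -0.63 (SE 0.17; -0.24 with normexp). These 3 calls were lost within slide 1, without treated replicate 3 (adjusted p = 0.0883, 0.0599 and 0.662, medians -0.35, -0.05 and -0.01). The ribosomal median was -0.15 with quantile scaling (33 of 35 lower) and -0.12 with median scaling (32 lower), and -0.10 without treated replicate 2. The PPARA call was also lost without vehicle replicate 1 (adjusted p = 0.193) and without vehicle replicate 2 (adjusted p = 0.257), and it and the glucocorticoid call were lost with median scaling (adjusted p = 0.0919 and 0.0738). The PPARA median was -0.14 with median scaling and -0.16 without vehicle replicate 3.

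**Figure D3:**
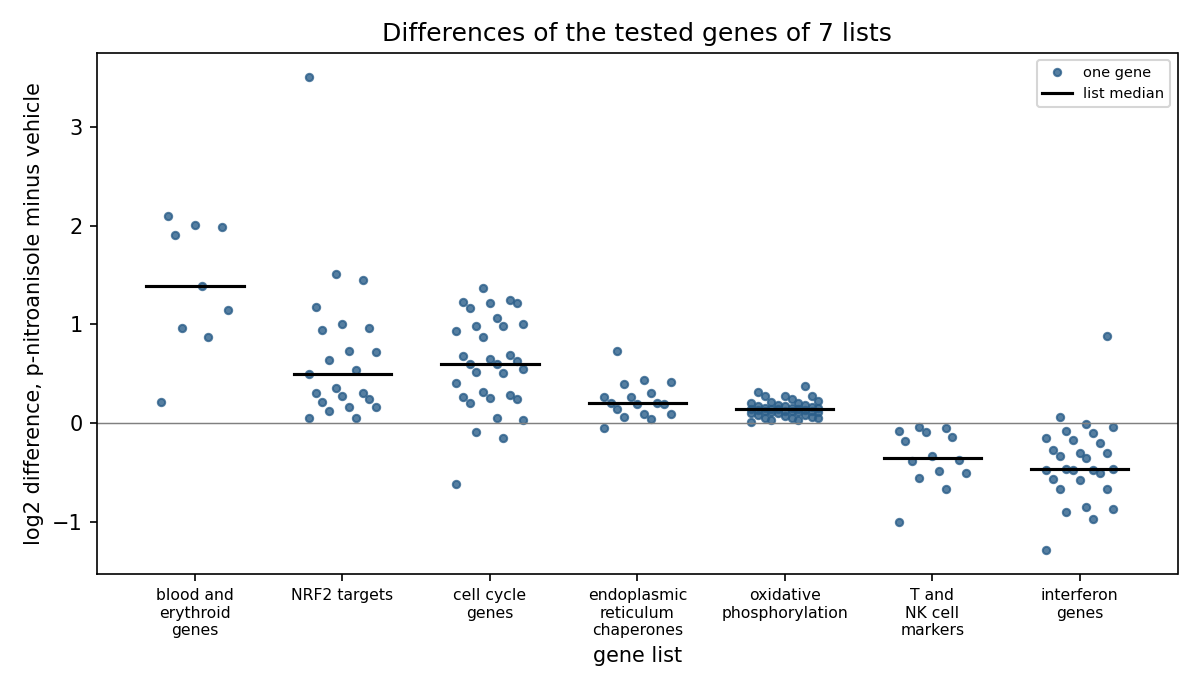
Log2 difference, p-nitroanisole minus vehicle, of each tested gene of 7 called lists (1 point per gene), with the list median as a bar. The medians run from 1.39 for red cell genes to -0.46 for interferon genes.

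The other 24 lists tested were not called, with camera adjusted p from 0.0531 for antigen presentation to 0.925 for vitamin D and phosphate genes. Antigen presentation (16 tested, 11 lower, median -0.17) was called lower within slide 1 (adjusted p = 0.0421, 14 lower), without vehicle replicate 1 (adjusted p = 0.000939) or 2 (adjusted p = 0.0425), with normexp (adjusted p = 0.00658), with no filter (adjusted p = 0.0241) and with probes well above background on all 6 arrays (adjusted p = 0.0428). With the replicate block it was called lower too (adjusted p = 0.0126). It was not called with quantile scaling (adjusted p = 0.0849), with median scaling (adjusted p = 0.129) or without treated replicate 1 (adjusted p = 0.460) or 2 (adjusted p = 0.0508). Its median was -0.28 without vehicle replicate 1 and -0.01 without vehicle replicate 3, where 8 of 16 were lower (adjusted p = 0.380). Kidney injury markers (31 tested, 20 lower, median -0.06) had an adjusted p of 0.400, with Krt19 at -1.29 (SE 0.85; -0.30 within slide 1) and Fgg at 0.98 (SE 0.43; 0.31 with normexp). Another member of that list was the 1 that was higher when adjusted over the list alone. Among proximal tubule enzymes (38 tested, median 0.09, adjusted p = 0.432) Cyp2e1 was called lower, and among heme and iron genes (27 tested, median 0.01, adjusted p = 0.870) Hmox1 was called higher. Among p53 targets (23 tested, adjusted p = 0.125) Gdf15 differed by 1.29 (SE 0.20), and among adrenal genes (5 tested, adjusted p = 0.0927) Hsd3b1 differed by 1.47 (SE 0.27) and Cyp11a1 by 1.16 (SE 0.33; 0.49 with normexp), both also higher when adjusted over the list alone. Clock genes (16 tested, adjusted p = 0.266) included Nr1d1 at 1.12 (SE 0.46) and Per1 at -0.74 (SE 0.55; -0.24 on its second probe), from -0.27 without vehicle replicate 2 to -1.34 without vehicle replicate 3.

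Markers of podocytes (adjusted p = 0.104), endothelium (0.400), thick ascending limb (0.544), distal convoluted tubule (0.898), intercalated cells (0.356), medulla (0.238), adipocytes (0.870) and B and plasma cells (0.204) were not called. Nor were CAR and PXR targets (0.435), complement and coagulation genes (0.165), cytokines and chemokines (0.774), hypoxia genes (0.467), the integrated stress response (0.893), heat shock genes (0.726), immediate early genes (0.630) or renin angiotensin genes (0.130). These are camera adjusted p values at the preset correlation. Among the alternatives, 3 called the podocyte list and 2 the complement list lower, 2 the adrenal list higher, and 1 each the B and plasma cell list lower and the renin angiotensin list higher. The mean, the median and the test differed in sign for the thick ascending limb, distal convoluted tubule, integrated stress response and cytokine lists. The list of AhR targets had 4 tested members, too few for the test, and Nqo1 at 0.96 (SE 0.21) and Ahrr at -0.78 (SE 0.39; -0.46 and -1.21 without treated replicates 1 and 2) differed most.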

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

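The normexp alternative below, run on the median spot and background signals, was chosen after the files were seen, because the planned one on mean signals was not run: the files hold no mean signal column. All 24 rows kept their direction under the alternatives in which they were tested, and none of the named genes called in either setting changed sign. For the 24 rows, leaving out 1 array could not change the direction, because their groups did not overlap. The number of genes changed by p-nitroanisole was 24 (16 higher, 8 lower, 16 with a log2 difference of at least 1). It was 82 with normexp (74 higher, 34 with a log2 difference of at least 1), 316 with a trended robust variance (277 higher, 39 lower, 73 of at least 1), 2 with no filter (2 higher, 0 lower, 2 of at least 1) and 0 in every count at a threshold of 0.01, where the same limma fit has 4327 rows at an unadjusted p under 0.05. With probes well above background on all 6 arrays, 27 were higher. With slide as a block it was 9 (7 higher, 2 lower, 9 of at least 1), by construction the comparison without treated replicate 3. Leaving out 1 array at a time gave 0 to 9 rows, 0 to 7 higher, 0 to 2 lower and 0 to 9 of at least 1; those fits have fewer samples. For the other settings the cause was not tested. Quantile scaling, median scaling and the series matrix values called 19, 20 and 22 rows, all among the 24, and moved the median of all genes by at most 0.06. The replicate numbers did not pair the samples: deviations of same-numbered arrays correlated at -0.009, 0.040 and -0.010. With the replicate block limma called 1 row, 0 higher and 1 lower, 1 of at least 1, in a fit with fewer residual degrees of freedom, and camera called 20 lists, all 18 among them. Camera called 0 lists with an estimated correlation and 15 to 20 under the other alternatives, with 0 calls reversed. The estimated correlation had a median of 0.0988 over the lists, against the preset 0.01. It was 0.673 for red cell genes and 0.407 for cell cycle genes. For the conjugation, fatty acid synthesis and glucocorticoid lists it was -0.0012, -0.0675 and -0.0299, below the preset, and those calls were lost too. A correlation above the preset therefore does not account for every lost call. The adjusted p with an estimated correlation thus does not reflect the correlation of genes alone. Probes well above background, 66.4% to 69.2% of an array, limit which genes could be tested.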

Other observations

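All tests in this part, including the counts over other splits of the arrays, were chosen after the results they measure were seen.

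Of the 4 tested Ugt2b genes, which code for glucuronosyltransferases, 3 had similar differences on the probe with the highest level: Ugt2b37 at 2.13 (SE 0.16, adjusted p = 0.0404), Ugt2b15 at 2.07 (SE 0.25) and Ugt2b35 at 1.98 (SE 0.24), the last 2 with adjusted p = 0.0805. Ugt2b7 was at 0.04 (SE 0.26) and at -0.01 with median scaling. The second probes of Ugt2b37 and Ugt2b15 gave less, 0.40 (SE 0.22) and 1.28 (SE 0.20), so the similarity does not hold over all probes. Related Ugt2b probes can share sequence. The amino acid transporter genes Slc38a3 and Slc38a5 differed by 1.60 (SE 0.19, adjusted p = 0.0805) and 1.52 (SE 0.16, adjusted p = 0.0622), short of the threshold. Of the 8 tested Slc38a genes 5 were higher and 3 lower, and the others lay between -0.39 (Slc38a1) and 0.06 (Slc38a8). The Klra genes, NK cell receptors, were lower in 4 of 4 tested, with Klra1 at -1.50 (SE 0.49, adjusted p = 0.299) and Klra5 at -1.49 (SE 0.65, adjusted p = 0.401), none of them past the threshold. The sizes depended on the background correction: with normexp Klra1 was at -0.31 (SE 0.09) and Klra5 at -1.24 (SE 0.53).

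Of the 10 splits of the 6 arrays into 3 and 3, 1 called as many as 24 rows, the real one, and the highest of the others called 1. For gene lists 1 of the 10 called as many as 18, again the real one. Each of the others called 3 to 9 lists. Those splits mixed the groups in unequal shares, so part of any treatment difference stayed in the comparison and part added to the spread. Their counts of rows and lists therefore do not measure false calls. With 10 splits no share can fall under 0.1, too high for the 0.05 needed to exclude chance.

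Red cell genes rose, and if the treated tissue only held more blood of unchanged composition, the globins and the other red cell genes should rise alike. The 6 other red cell genes rose by 0.88 more than the 3 globins on the log2 scale (1.84 against 0.96, SD over arrays 0.35). Each treated array lay above each vehicle array in this difference, no spot was saturated and spike-in slopes were 0.974 to 1.02. The difference was not measured with normexp, where the median of the whole list was 1.06 against 1.39. It therefore cannot decide the question. The second slide is argued against, since the list medians of the 2 treated arrays of slide 1 averaged 1.16 above those of the vehicle arrays. More blood in the tissue and effects of the treatment stay open, and no test here tells them apart.

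Cell cycle genes rose. A gain of T, NK or B cells or macrophages is argued against on treated replicates 1 and 3, where the median of their 33 markers was -0.37 and -0.49 (mean -0.43, vehicle SD 0.04), but stays open on treated replicate 2, where it was -0.0737 and the cell cycle median was the highest at 0.68. The size of the fall depends on the background correction. With normexp the median difference was -0.09 for T and NK cells (-0.35 without it), -0.13 for B and plasma cells (-0.29) and -0.31 for macrophages (-0.32). The second slide is argued against as well, since the list medians of the 2 treated arrays of slide 1 averaged 0.61 above those of the vehicle arrays. Dividing red cell precursors cannot be told apart from other sources: the treated array with the highest red cell genes, by 0.40, had cell cycle genes 0.0147 above the mean of the other 2 (vehicle SD 0.09), a comparison that rests on 1 array. Neutrophil precursors and cells of the tubule stay open as sources, and as effects of the treatment.

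The position of the arrays bears on all called lists, and within slide 1, 14 of the 18 kept their call and direction, which argues against the second slide as their cause. Glucocorticoid targets lost the call in that fit, which has 1 array fewer (camera adjusted p = 0.0883). On the treated arrays of slide 1 the list medians were -0.30 and -0.23 (on average -0.29 against vehicle, vehicle SD 0.03), so a shift was present without the second slide. The tests of the red cell and cell cycle lists also asked for a call within slide 1. Without that call, slide and treatment cannot be told apart for the call of glucocorticoid targets. For T and NK cell markers (median difference -0.35 over all arrays, -0.20 within slide 1), ribosomal proteins (-0.07 and -0.05) and PPARA targets (-0.09 and -0.01) both treated arrays of slide 1 lay past 2 vehicle SD in 0 of 3 lists, so slide and treatment cannot be told apart. Slide 1 held the vehicle arrays in row 1 and treated replicates 1 and 2 in row 2, while treated replicate 3 was in row 1 of slide 2. In 18 of the 18 lists treated replicate 3 lay outside the vehicle range in the called direction, but this is 1 array, so the row of the slide and the treatment cannot be told apart.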
